A study of Homo sapiens with 21 samples.

How the data were processed

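The data are 21 arrays of total RNA from 4 human breast cancer cell lines, with 12 groups made of 4 lines and 3 doses (DMSO, 50 and 250 nM THZ1 for 6 hours). MDA-MB-468, ZR-75-1 and T47D have 2 arrays per group and BT-549 has 1. Per the labels' protocols, cells grew in serum-supplemented RPMI-1640, total RNA was extracted on columns with DNase treatment, an ERCC spike-in mix was added in proportion to cell number, and a fixed mass of total RNA was amplified from oligo(dT) primers and labelled with biotin for 3' expression arrays. Sample titles and the cell line field gave each group and the replicate number. The source name field of the ZR-75-1 and T47D samples names another line, and the DMSO arrays were compared between lines to check the labels.

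The deposited values are linear probe set intensity, 1 value per probe set and array, from 0.932 to 28797 over 49395 probe sets. Per the submitters' processing notes MAS5 was used, with no version, and how arrays were scaled to each other is not given in the sources used here. The array means lie close together and the trimmed means do not coincide (178.5 to 228). All 21 columns were used. Through the platform annotation 44994 probe sets have 1 gene symbol, 1832 have several and were not used to name a gene, and 2569 have no entry there, 102 of the table's probe sets being Affymetrix controls. Symbols were updated through the Entrez identifier for 44967 probe sets. No probe set is named for an ERCC transcript, so the planned scaling to the spike-in mix was not run. A gene was represented by the probe set with the highest mean over all arrays, and called probe sets that went the opposite way are given beside a named gene. Where no array of a group lay above the mean of its 23 background probe sets, the fold is a bound ("at least"), taken against the higher of gene and background per array, a step added after the data were seen.

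Values were raised to a floor of 1 and taken to log2 without further scaling. This was planned because the spike-in was added by cell number, and a rescaling could remove a change in RNA per cell. However, a fixed mass of total RNA was amplified, and the array means lay between 326.4 and 342.8. The values as deposited may therefore not hold such a change either, and counts of lower and higher genes are not counts per cell. Genes were kept where the highest group mean reached the median of all values (log2 5.84, an intensity of 57.4), which left 12644 of 18132 genes. limma 3.58.1 in R 4.3.3 fitted 9 group means on the 18 arrays of the 3 replicated lines (lmFit, eBayes with trend, 9 residual and 6.18 prior degrees of freedom). The contrasts were each dose against DMSO and 250 against 50 nM within a line, the change in MDA-MB-468 minus the mean change of ZR-75-1 and T47D, and the DMSO arrays of MDA-MB-468 minus those of the ER+ lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast, and counts with at least a 2-fold change stand beside. The response shared by 4 lines and the difference between 2 TNBC and 2 ER+ lines were fitted with limma on 12 line-by-dose means, with the line as a term (6 and 4 residual degrees of freedom). BT-549 has no test, and medians of gene lists there were set against 10000 random lists of the same size drawn within 20 bins of mean expression.

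The groups, contrasts, gene lists and the rule for naming genes were chosen before the data were examined. The rule takes, per line and dose, the 8 most negative and 4 most positive changes among called genes whose 2 treated arrays lie beyond both DMSO arrays, 11 fixed genes (MYC, EGFR, FOSL1, SOX9, FOXC1, MCL1, CDK7, ESR1, GATA3, FOXA1 and CCND1, of which 10 were tested), up to 4 members per list by moderated statistic, and 8 genes per direction for differences between lines. H2AC17 in MDA-MB-468 and the genes of the 4-line and subtype comparisons were named after their values were seen, as the largest changes there. The 29 lists comprise TNBC-associated regulators, luminal and ER-linked genes, basal and mesenchymal markers, immediate early genes, anti-apoptotic genes, pro-apoptotic genes, G2/M genes, G1/S and replication genes, DNA damage response genes, TFIIH and transcription kinase genes, RNA polymerase II subunits, Mediator subunits, p53 targets, heat shock genes, unfolded protein and amino acid stress genes, EGFR and MAPK feedback genes, TGF-beta, WNT and NOTCH genes, NF-kB and cytokine genes, interferon response genes, cholesterol synthesis genes, immune and stromal markers, housekeeping genes, and, by symbol pattern, cytosolic ribosomal protein, mitochondrial ribosomal protein, oxidative phosphorylation, proteasome subunit, ZNF-named zinc finger, replication-dependent histone and HOX genes. They were tested with limma's camera at a preset correlation of 0.01, adjusted over 29 lists and 11 contrasts (319 tests). Camera compares a list with the other genes, and its calls that hold with an estimated correlation are those of oxidative phosphorylation and histone genes at 250 nM in MDA-MB-468 and ZR-75-1, the same lists for 250 against 50 nM in ZR-75-1, TGF-beta, WNT and NOTCH genes for 250 against 50 nM in MDA-MB-468, and TNBC-associated regulators in the difference at 250 nM.

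The alternatives were median-centred arrays, quantile normalization, no filter, a filter at the 75th percentile, a floor of 16, the mean of a gene's probe sets, each probe set alone, no trend, array weights, the 6 arrays of a line alone, the replicate number as a block, camera with an estimated correlation, fry, leaving out each array and leaving out each line. Scaling to the control probe sets lys, TagJ and TagO, genes at the filter level in DMSO of each line, a crossed replicate block in ZR-75-1 and other scalings of the DMSO comparison were added after the data were seen. The fits were tested on simulated data with 200 changed genes of 12644. In the MDA-MB-468 contrasts 97% (50 nM) and 91% (250 nM) of the genes changed 2-fold and 68% and 75% of those changed 1.5-fold were recovered, with 9 and 10 unchanged genes called, and 0 were called by limma in an unchanged T47D contrast. For the response shared by 4 lines at 250 nM 97.5% of genes lowered by 1.5 log2 were recovered with 18 unchanged genes called, and for the subtype difference 96% of genes differing by 3 log2 with 7. Smaller changes were not simulated in these 2 comparisons. Arrays have no read depth, and the number of arrays limits the precision, the median SE of a log2 change being 0.11.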

Results

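RNA levels were measured on 21 Affymetrix PrimeView arrays in 4 established human breast cancer cell lines exposed for 6 hours to the solvent DMSO or to 50 or 250 nM THZ1, a covalent inhibitor of CDK7, the kinase of the general transcription factor TFIIH. The series asks how far triple-negative breast cancer (TNBC) cells depend on CDK7 for transcription. MDA-MB-468 and BT-549 are TNBC lines, and ZR-75-1 and T47D express the oestrogen receptor (ER+). MDA-MB-468, ZR-75-1 and T47D had 2 arrays per dose. BT-549 had 1 array per dose, so its values are given without a test. The mean intensity per array lay between 326.4 and 342.8, whereas the 75th percentile ranged from 140.3 to 231.2. In ZR-75-1 that percentile was 203.6 ± 4.74 with DMSO and 143 ± 3.82 at 250 nM (SD, n = 2). In MDA-MB-468 and T47D it went from 225 ± 8.84 and 226.4 ± 1.84 to 180.8 ± 3.25 and 181.8 ± 6.01. Replicate arrays correlated at r = 0.9941 to 0.9965 across probe sets, which are not independent replicates. Between 7 and 30 of 12644 genes differed 2-fold between replicates. The labels do not say that replicates were separate cultures, so p-values measure the spread between these arrays, which may be technical, and their small number limits the precision.

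With DMSO, the lines differed in the markers of their subtypes. The oestrogen receptor gene ESR1 had an intensity of 441.6 ± 9.32 in ZR-75-1 and 906 ± 30.4 in T47D (SD, n = 2), against 30.88 ± 2.48 in MDA-MB-468 and 18.45 on the BT-549 array. GATA3 and FOXA1, transcription factors of luminal cells, stood at 4745 ± 770 and 3632 ± 180 in ZR-75-1 and at 327.6 ± 4.28 and 277.2 ± 21.8 in MDA-MB-468, with 139.2 and 15.07 in BT-549. MDA-MB-468 had high EGFR, the epidermal growth factor receptor (4267 ± 73.1), and the basal keratin KRT5 (3505 ± 15.2). BT-549 had high VIM, the mesenchymal filament vimentin (14440), with the epithelial cadherin CDH1 at 34.92. The luminal and ER-linked list had a median log2 level of 7.26 and 7.49 on the MDA-MB-468 arrays, 6.05 in BT-549, 9.44 and 9.55 in ZR-75-1, and 10.86 on each T47D array. Markers of immune and stromal cells lay between 5.63 and 5.88 on every DMSO array. Between MDA-MB-468 and the mean of the ER+ lines, 4346 genes were lower and 4188 higher (limma, adjusted p under 0.05). ESR1 was lower in MDA-MB-468 by a log2 difference of -4.36 ± 0.13 (SE, limma adjusted p = 6.34e-14). 1 label field names MDA-MB-468 for the ZR-75-1 and T47D samples, against their titles and cell line fields. The marker levels differed as those titles state.

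In MDA-MB-468, 50 nM THZ1 lowered the xenobiotic-metabolising enzyme CYP1A1 17.4-fold (log2 change -4.12 ± 0.13, SE, n = 2 against 2, limma adjusted p = 2.34e-11). Other genes that fell were ZC3H4 (-2.44 ± 0.12), a zinc finger protein, NABP1 (-2.41 ± 0.16), which binds single-stranded DNA, KRCC1 (-2.23 ± 0.11) and the E2F family repressor E2F8 (-2.18 ± 0.19). So did the Integrator subunit INTS6 (-2.10 ± 0.09), MOCS3 (-2.10 ± 0.14) and the 3' end processing factor PCF11 (-2.04 ± 0.14). The chromatin protein gene PHF12 rose 4.17-fold (2.06 ± 0.13), ahead of DMXL1 (1.55 ± 0.11), TENT5C (1.54 ± 0.19), which encodes a poly(A) polymerase, and ZMYM5 (1.31 ± 0.11). Other probe sets went the opposite way for 3 of these genes, 1 of 6 for INTS6, 1 of 2 for PHF12 and 2 of 3 for DMXL1. The transcription factor genes MYC (-0.72 ± 0.08) and SOX9 (-0.36 ± 0.08) and the cyclin gene CCND1 (-0.31 ± 0.06) were lower. MCL1, an apoptosis inhibitor, was at -0.05 ± 0.09 (limma adjusted p = 0.738). Both treated arrays lay beyond both DMSO arrays for each gene named here by its rank. limma called 1844 genes lower and 559 higher, 192 and 18 of them by at least 2-fold. The median change over all genes was -0.06. Centring each array on its median moved that median to 0.08, turned the split to 1053 lower and 1605 higher and ended the calls of SOX9 (-0.22) and CCND1 (-0.17). Left out in turn, DMSO array 1, 50 nM array 1 and 50 nM array 2 took the higher genes to 217, 231 and 250, and 50 nM array 2 took the lower ones to 1189.

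At 250 nM, MDA-MB-468 lost most of its MYC signal, from 1880 ± 47.9 to 100.1 ± 9.65 intensity units (SD, n = 2), 18.8-fold (log2 change -4.23 ± 0.08, SE, limma adjusted p = 2.98e-14). The matrix-associated growth regulator CCN1 fell 20.9-fold (-4.38 ± 0.09), the secreted WNT antagonist DKK1 19.9-fold (-4.31 ± 0.14), the forkhead factor FOXQ1 18.4-fold (-4.20 ± 0.16) and the transcription co-regulator CITED2 17.6-fold (-4.13 ± 0.14). CYP1A1 (-4.01 ± 0.13), the anaphase-promoting complex inhibitor FBXO5 (-3.80 ± 0.12) and the adhesion scaffold NEDD9 (-3.75 ± 0.22 as measured) followed, the last being at least 12.5-fold lower, as its treated arrays were not above background. SOX9 was 7.22-fold lower (-2.85 ± 0.08), FOXA1 5.31-fold (-2.41 ± 0.08), MCL1 3.94-fold (-1.98 ± 0.09), and GATA3 2.63-fold (-1.40 ± 0.09). CDK7 itself was 1.91-fold lower (-0.93 ± 0.07), with CCND1 at -0.64 ± 0.06 and EGFR at -0.28 ± 0.07 (limma adjusted p = 0.00469). FOSL1, an AP-1 subunit (2 of 6 probe sets opposite), and ESR1 stood at 0.03 ± 0.17 and -0.05 ± 0.15, which did not pass. 5 genes rose at least 2-fold, the histone genes H2BC8 (3.64-fold, 1.86 ± 0.13), H2AC8 (1.22 ± 0.10) and H2AC17 (1.06 ± 0.13), the small nucleolar RNA SNORA65 (1.45 ± 0.16) and, as measured, BPIFA1 (1.19 ± 0.33). BPIFA1 was not above background in DMSO (log2 4.25 against 4.67), so its rise is bounded only as at least 1.71-fold. RNA was amplified from oligo(dT) primers, so histone and SNORA65 values here and below cover only RNA that these primers copied. Total RNA of these genes was not measured. limma called 3834 genes lower, 1343 of them at least 2-fold, and 1206 higher. Median-centred arrays gave 2745 lower and 3479 higher, with the median change moved from -0.07 to 0.14 and the call of EGFR ended (-0.08). Quantile normalization gave 2871 and 3092. The higher genes numbered 746 without DMSO array 1 and 789 without 250 nM array 2. Those at least 2-fold higher were 10 without either DMSO array.

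ZR-75-1 responded to 50 nM with fewer calls, led by KRCC1, 3.6-fold lower (log2 change -1.85 ± 0.11, SE, n = 2 against 2, limma adjusted p = 8.92e-08). CYP1A1 (-1.63 ± 0.13) and its relative CYP1B1 (-1.60 ± 0.06) fell with INTS6 (-1.54 ± 0.09), the delta tubulin gene TUBD1 (-1.53 ± 0.10), LMCD1 (-1.53 ± 0.12), FAM135A (-1.42 ± 0.18, 1 of 2 treated arrays not above background) and the replication fork protein gene MMS22L (-1.33 ± 0.11). PHF12 rose 3.42-fold (1.77 ± 0.13, uncalled probe set -0.07), ANKRD36 2.95-fold (1.56 ± 0.15), SSH1 2.63-fold (1.39 ± 0.13) and SNAPC3 2.45-fold (1.29 ± 0.11). 1 of 6 probe sets of INTS6 and 1 of 4 of SSH1 went the opposite way. MYC was at -0.16 ± 0.08 (limma adjusted p = 0.281). CCND1 was lower at -0.25 ± 0.06 (limma adjusted p = 0.014). This call ended after median-centring (-0.23) and without DMSO array 1 (-0.24), DMSO array 2 (-0.26) or 50 nM array 2 (-0.19). limma called 718 genes lower and 353 higher, 25 and 7 of them at least 2-fold. Arrays scaled to the control transcripts lys, TagJ and TagO gave 268 lower and 431 higher. Leaving out 1 array at a time, the lower genes numbered 388 without DMSO array 1, 413 without DMSO array 2 and 361 without 50 nM array 2. The higher ones numbered 216, 175 and 192 without these same arrays and 135 without 50 nM array 1. Without 50 nM array 2, 40 genes were at least 2-fold lower.

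At 250 nM, ZR-75-1 had the most genes past the threshold of these 6 contrasts against DMSO, with 5406 lower, 2285 of them at least 2-fold, and 1256 higher (limma). ZC3H4 fell 16.2-fold (log2 change -4.02 ± 0.12, SE, n = 2 against 2, limma adjusted p = 4.04e-13), and MOCS3, which activates sulphur for cofactor and tRNA synthesis, fell at least 14.5-fold (-3.89 ± 0.14 as measured), its treated arrays not being above background. E2F8 and MTFR2 were each 13.3-fold lower, CASP8AP2, a factor of histone messenger processing, was at -3.70 ± 0.17. DKK1, the eIF2alpha phosphatase subunit PPP1R15B and ZBED5 were at -3.67 ± 0.14, -3.67 ± 0.11 and -3.65 ± 0.10. FOXA1 was 5.02-fold lower (-2.33 ± 0.08), MYC 4.89-fold (-2.29 ± 0.08), MCL1 3.47-fold (-1.80 ± 0.09), and CCND1 3.27-fold (-1.71 ± 0.06). GATA3 was 3.12-fold lower (-1.64 ± 0.09), CDK7 2.38-fold (-1.25 ± 0.07), SOX9 2.01-fold (SE 0.08), ESR1 1.83-fold (-0.87 ± 0.15) and EGFR 1.74-fold (-0.80 ± 0.07, 1 of 2 treated arrays not above background). EID3 (1.70 ± 0.31, from a DMSO level of log2 4.79 next to background at 4.76), H2AC17 (1.36 ± 0.13), the long noncoding RNA MALAT1 (1.31 ± 0.16, 1 of 3 probe sets opposite) and H2BC8 (1.24 ± 0.13) were higher. The median change was -0.18 as deposited and 0.08 after median-centring, which gave 3986 lower and 3625 higher genes. With quantile normalization there were 3857 and 4189. Without 250 nM array 2, 10 genes rather than 6 were at least 2-fold higher.

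**Figure D1:**
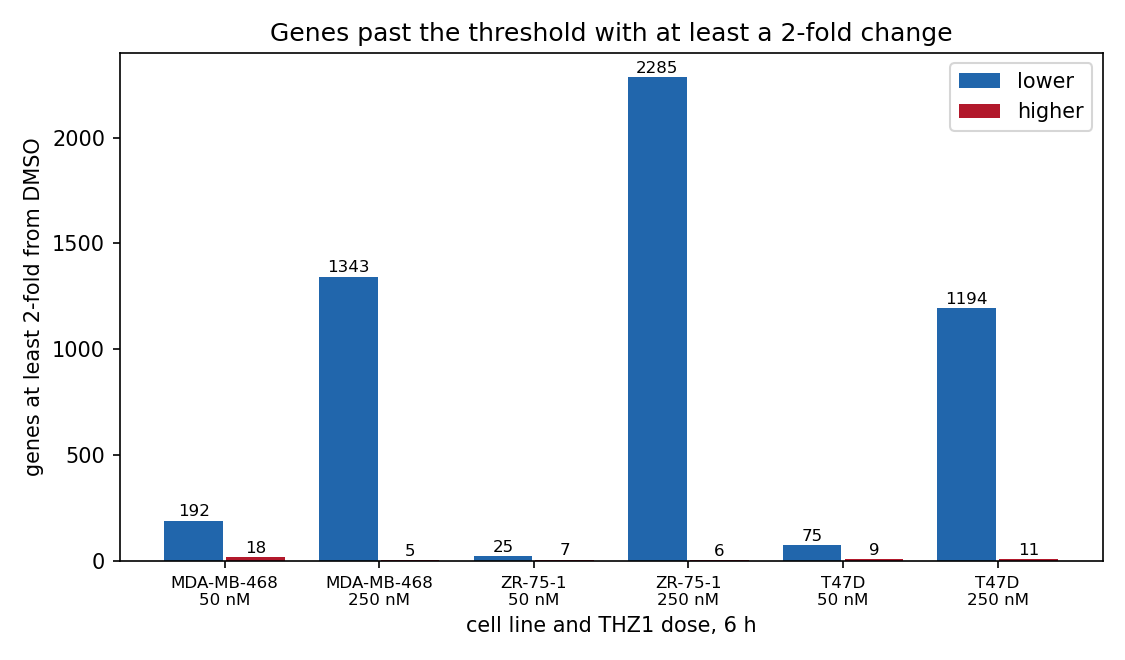
Bars give the number of genes at least 2-fold lower or higher than with DMSO at 50 and 250 nM THZ1, called at a limma adjusted p under 0.05 in the 3 replicated lines. The counts given here for BT-549 rest on the size of the change alone. The lower genes number 1343, 2285, 1194 and 1130 at 250 nM in MDA-MB-468, ZR-75-1, T47D and BT-549, against 5, 6, 11 and 23 higher genes.

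T47D at 50 nM showed CYP1A1 11.8-fold lower (log2 change -3.56 ± 0.13, SE, n = 2 against 2, limma adjusted p = 3.29e-10) and NEDD9 5.27-fold lower (-2.40 ± 0.22). KRCC1 (-2.31 ± 0.11 as measured, at least 4.5-fold, its treated arrays not being above background), WDR5B (-1.90 ± 0.19), CEP19 (-1.80 ± 0.18), PCF11 (-1.74 ± 0.14), TUBD1 (-1.61 ± 0.10) and XYLT1, a proteoglycan xylosyltransferase (-1.59 ± 0.32), also fell. PHF12 (1.80 ± 0.13, uncalled probe set -0.54), ANKRD36 (1.59 ± 0.15) and NFATC1 (1.31 ± 0.11, uncalled probe set -0.26) rose. So did RBM34 (1.29 ± 0.25, DMSO level log2 4.82 next to background at 4.69) and EGFR (0.36 ± 0.07, limma adjusted p = 0.00465, 1 of 6 probe sets opposite). MYC was at -0.11 ± 0.08 (limma adjusted p = 0.496). limma called 956 genes lower and 252 higher, 75 and 9 of them at least 2-fold. Quantile normalization gave 710 lower and 532 higher, and scaling to lys, TagJ and TagO gave 4133 and 68. Without DMSO array 1, DMSO array 2, 50 nM array 1 or 50 nM array 2 the lower genes numbered 443, 492, 468 and 632 and the higher ones 115, 132, 130 and 141. XYLT1 lost its call without 50 nM array 1 (-1.43) and EGFR without DMSO array 2 (0.33) or 50 nM array 2 (0.27).

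At 250 nM, T47D had CYP1A1 14.4-fold lower (log2 change -3.85 ± 0.13, SE, limma adjusted p = 1.63e-11), with E2F8 (-3.66 ± 0.19 as measured, at least 10.1-fold, its treated arrays not being above background), MOCS3 (-3.48 ± 0.14), the growth factor response gene PHLDA1 (-3.31 ± 0.11), ZC3H4 (-3.23 ± 0.12), the insulin receptor substrate gene IRS1 (-3.18 ± 0.09), LRIF1 (-3.07 ± 0.19) and PCF11 (-3.05 ± 0.14, 1 of 2 treated arrays not above background). MYC was 4.53-fold lower (-2.18 ± 0.08), FOXA1 2.75-fold (-1.46 ± 0.08), MCL1 2.34-fold (-1.23 ± 0.09), SOX9 2.2-fold (-1.14 ± 0.08) and CDK7 1.66-fold (-0.73 ± 0.07). Smaller falls were those of GATA3 (-0.34 ± 0.09), CCND1 (-0.26 ± 0.06), ESR1 (-0.38 ± 0.15, limma adjusted p = 0.0491) and EGFR (-0.22 ± 0.07, limma adjusted p = 0.0233). ANKRD36 (1.67 ± 0.15), PHF12 (1.65 ± 0.13, 1 of 2 probe sets opposite), RBM34 (1.33 ± 0.25) and the phosphatase gene PTPN14 (1.26 ± 0.15) were higher. limma called 4256 genes lower, 1194 of them at least 2-fold, and 1215 higher. Median-centring gave 3279 and 2453 and ended the calls of GATA3 (-0.22), CCND1 (-0.14), ESR1 (-0.26) and EGFR (-0.09). Quantile-normalized arrays gave 3030 and 3361 and put EGFR at 0.09. The higher genes numbered 712 without DMSO array 1, which left 17 genes at least 2-fold higher, and 664 without 250 nM array 2. EGFR lost its call without either DMSO array (-0.19 and -0.24) or either 250 nM array (-0.22 each). ESR1 lost it without either DMSO array (-0.35 and -0.42), either 250 nM array (-0.29 and -0.48) or, at an unmoved -0.38, either T47D 50 nM, ZR-75-1 DMSO or MDA-MB-468 250 nM array.

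**Figure D2:**
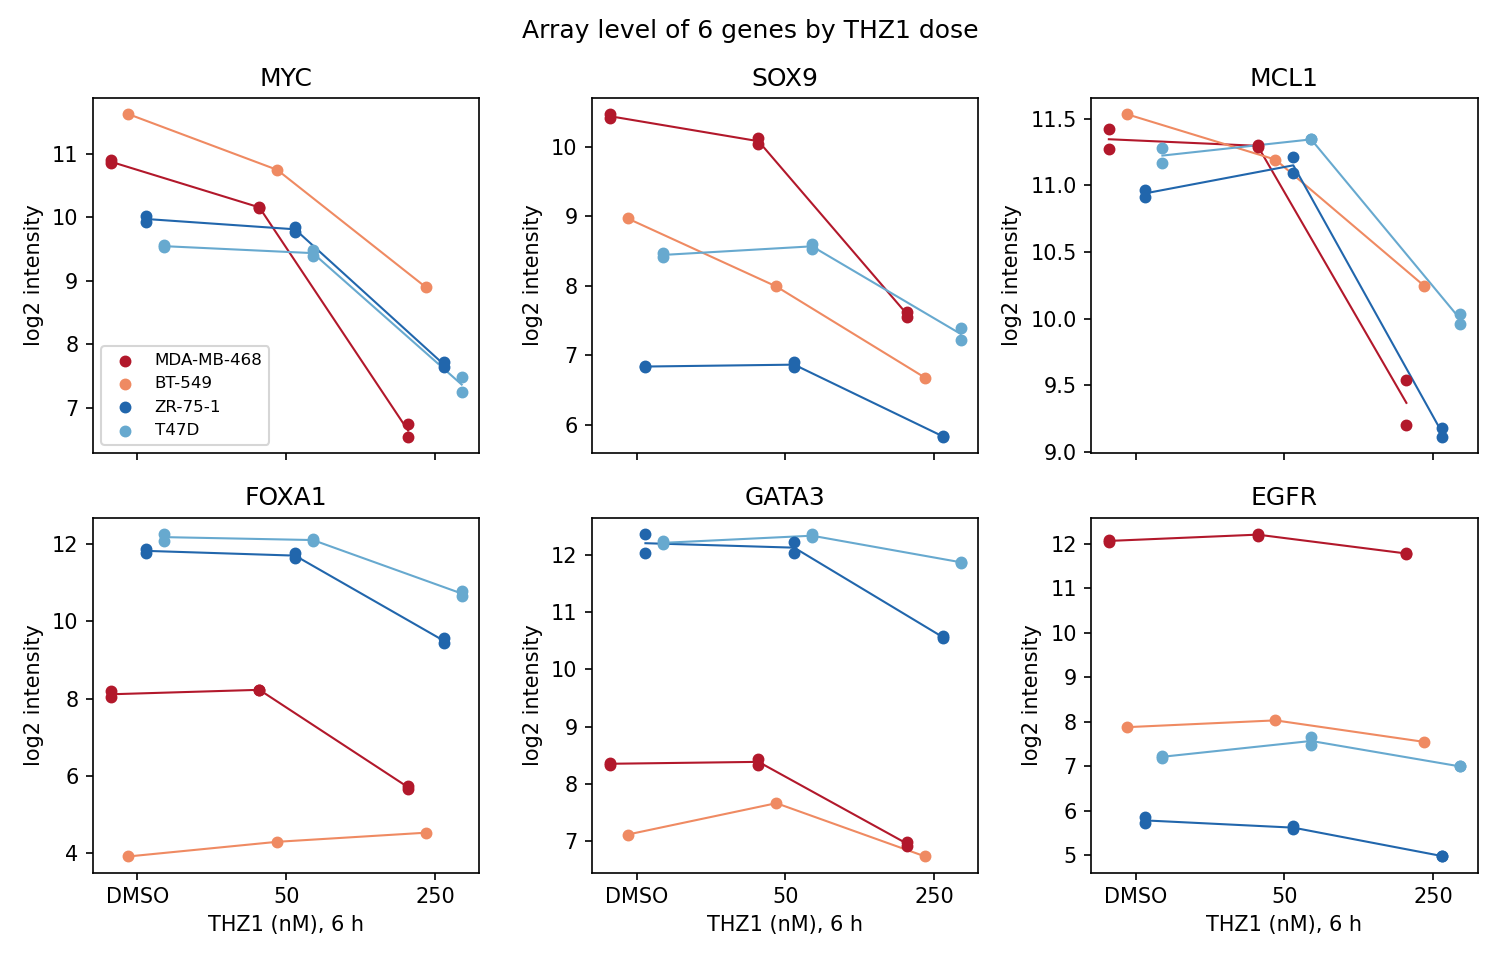
Points give the log2 intensity of MYC, SOX9, MCL1, FOXA1, GATA3 and EGFR on each array at 0, 50 and 250 nM THZ1 in the 4 lines, and lines join the group means. MYC is lower at 250 nM in each line, with log2 changes of -4.23, -2.29, -2.18 and -2.73 in MDA-MB-468, ZR-75-1, T47D and BT-549.

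Gene groups were compared with the other genes of the array with limma's camera. Immediate early genes, which respond to growth factors within minutes, were lower at 250 nM, namely 23, 23 and 20 of 33 measured members in MDA-MB-468, ZR-75-1 and T47D over all genes and 24, 23 and 20 adjusted over the list alone. Their median changes were -1.49, -1.15 and -0.45, with the stress kinase gene PLK2 at -3.58 ± 0.11, -2.35 ± 0.11 and -2.00 ± 0.11 and the AP-1 gene JUN at -2.21 ± 0.13 in ZR-75-1 and -2.97 ± 0.13 in T47D. The list passed camera (adjusted p = 4.47e-09, 0.00025 and 0.00527) but not with an estimated correlation (adjusted p = 0.0762, 0.236 and 0.319). Genes of EGFR and MAPK feedback fell as well, 15, 16 and 13 of 24 (the same counts adjusted over the list alone). Among them were PHLDA1 at -3.34 ± 0.11 in MDA-MB-468 and the MAPK phosphatase gene DUSP4 at -1.42 ± 0.07, -2.41 ± 0.07 and -1.41 ± 0.07. Their camera adjusted p was 2.69e-05, 0.0146 and 0.0183, and adjusted p = 0.0661, 0.236 and 0.239 with an estimated correlation. In MDA-MB-468, 22 of 30 genes of TGF-beta, WNT and NOTCH signalling (22 adjusted over the list alone) and 12 of 21 NF-kB and cytokine genes (12 adjusted over the list alone) were lower. They included SMAD6 (-1.90 ± 0.11), ID3 (-2.42 ± 0.14), the NF-kB inhibitor NFKBIA (-2.52 ± 0.09) and IRF1 (-2.93 ± 0.13). Camera gave these lists adjusted p = 0.000218 and 0.0283, and adjusted p = 0.0661 and 0.222 with an estimated correlation.

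ZNF-named zinc finger genes, mostly encoding DNA-binding repressors, formed the largest group, and 296, 311 and 290 of 381 were lower at 250 nM in MDA-MB-468, ZR-75-1 and T47D (305, 317 and 304 adjusted over the list alone), with medians of -1.02, -1.22 and -0.82. Examples were ZNF217 at -3.36 ± 0.12 in MDA-MB-468, ZNF146 at -2.47 ± 0.07 in ZR-75-1 and ZNF281 at -2.73 ± 0.14 in T47D. Camera adjusted p was 1.41e-20, 4.92e-14 and 8.82e-17, and adjusted p = 0.0541, 0.0671 and 0.0611 with an estimated correlation. Mediator subunits, which bridge activators and RNA polymerase II, fell in 16, 20 and 18 of 27 cases (17, 20 and 19 adjusted over the list alone), at camera adjusted p = 0.00538, 0.00209 and 0.00518 and adjusted p = 0.271, 0.239 and 0.27 with an estimated correlation. Genes of TFIIH and the transcription kinases did not pass as a group, although 10, 20 and 15 of 28 were lower (11, 20 and 16 adjusted over the list alone; camera adjusted p = 0.321, 0.121 and 0.0776). RNA polymerase II subunits had 6 of 12 members higher and 3 lower in ZR-75-1 (the same adjusted over the list alone). There camera put the list above other genes (adjusted p = 0.0456, and adjusted p = 0.348 with an estimated correlation) with a median of 0.15 but a mean of -0.05.

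Of 35 G2/M genes, 24, 25 and 20 were lower at 250 nM in MDA-MB-468, ZR-75-1 and T47D (27, 25 and 23 adjusted over the list alone). Examples were the mitotic kinase AURKA at -1.76 ± 0.06, -1.47 ± 0.06 and -0.96 ± 0.06 and the centromeric histone CENPA at -1.76 ± 0.11, -2.97 ± 0.11 and -1.50 ± 0.11. Of 38 G1/S and replication genes, 20, 24 and 19 were lower (20, 25 and 19 adjusted over the list alone), led by the cell cycle phosphatase CDC25A at -1.71 ± 0.07, -2.40 ± 0.07 and -1.20 ± 0.07. Camera adjusted p was 0.000163, 0.0084 and 0.00712 for G2/M and 0.00206, 0.00263 and 0.00667 for G1/S. With an estimated correlation these were adjusted p = 0.319, 0.456 and 0.442 and adjusted p = 0.251, 0.261 and 0.299. DNA damage response genes passed in ZR-75-1 and T47D, each with 20 of 29 members lower (20 adjusted over the list alone; camera adjusted p = 0.0147 and 0.000559, adjusted p = 0.261 and 0.135 with an estimated correlation). The checkpoint kinase WEE1 was at -3.28 ± 0.10, -2.67 ± 0.10 and -1.46 ± 0.10 in the 3 lines. Genes of the unfolded protein and amino acid stress response fell in MDA-MB-468 and ZR-75-1, 14 and 18 of 25 (14 and 18 adjusted over the list alone; camera adjusted p = 0.00825 and 0.037, adjusted p = 0.0918 and 0.16 with an estimated correlation).

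Genes of oxidative phosphorylation and of the cytosolic ribosome were slightly higher at 250 nM as deposited. The sign of their change turned with arrays scaled to lys, TagJ and TagO, where 8, 6 and 19 genes of all 12644 were higher in MDA-MB-468, ZR-75-1 and T47D. That scaling shifts all genes of an array alike and leaves the order of genes within it as it was. As deposited, 62, 68 and 43 of 79 oxidative phosphorylation genes were higher (67, 68 and 44 adjusted over the list alone) with medians of 0.24, 0.31 and 0.17. The ATP synthase subunit ATP5MK was at 0.42 ± 0.05, 0.45 ± 0.05 and 0.40 ± 0.05. Camera adjusted p was 1.03e-20, 3.82e-26 and 6.37e-15, and adjusted p = 0.0396, 0.0265 and 0.0544 with an estimated correlation. Of 69 cytosolic ribosomal protein genes, 41, 58 and 50 were higher (46, 61 and 53 adjusted over the list alone), with medians of 0.17, 0.26 and 0.19 (camera adjusted p = 2e-14, 4.5e-21 and 3.79e-14, adjusted p = 0.261, 0.184 and 0.263 with an estimated correlation). Replication-dependent histone genes, measured in RNA copied from oligo(dT) primers, had 9, 9 and 5 of 29 members higher (8, 9 and 3 adjusted over the list alone, camera adjusted p = 0.00025, 3.93e-07 and 0.00569, adjusted p = 0.0477, 0.0265 and 0.0671 with an estimated correlation). Housekeeping genes (9, 14 and 7 of 16 higher; 10, 14 and 7 adjusted over the list alone) and proteasome subunits (13, 15 and 7 of 33; the same adjusted over the list alone) passed camera at adjusted p up to 0.0377, and with an estimated correlation at no adjusted p under 0.0544. Quantile-normalized arrays ended the camera calls of the cytosolic ribosomal, housekeeping and proteasome lists in all 3 lines. Mitochondrial ribosomal protein genes in MDA-MB-468 were mixed, 18 higher and 16 lower of 74 (18 and 17 adjusted over the list alone), with a median of 0.06, a mean of -0.03 and a camera call upward (adjusted p = 0.0419, adjusted p = 0.586 with an estimated correlation).

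Markers of cell identity gave smaller group values. Of the 23 measured TNBC-associated regulators, a list partly drawn from knowledge of work on THZ1 and so not independent evidence of its direction, 10 were lower and 2 higher in MDA-MB-468 at 250 nM (the same adjusted over the list alone; camera adjusted p = 0.032, adjusted p = 0.136 with an estimated correlation). Among them were MYC, SOX9, FOXQ1 and the Krüppel-like factor KLF5 (-2.22 ± 0.11). FOXC1 was not tested, having no probe set of its own here. Luminal and ER-linked genes went both ways, with 10, 15 and 10 of 30 lower and 5, 7 and 6 higher in MDA-MB-468, ZR-75-1 and T47D (10, 15 and 11 lower and the same higher adjusted over the list alone; camera adjusted p = 0.534, 0.494 and 0.979). The luminal secretory factor XBP1 was at -1.55 ± 0.07 in MDA-MB-468 and -1.56 ± 0.07 in ZR-75-1. Basal and mesenchymal markers passed camera upward as deposited (adjusted p = 0.0131, 0.016 and 0.0131, and adjusted p = 0.319, 0.325 and 0.319 with an estimated correlation), although 3, 1 and 1 of 21 were called higher (3, 0 and 0 adjusted over the list alone). Immune and stromal markers passed camera upward in T47D (adjusted p = 0.0436, and adjusted p = 0.339 with an estimated correlation). Yet 1 of 14 members was called, in the lower direction (0 adjusted over the list alone). Quantile normalization ended the calls of the basal and of the immune and stromal lists.

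Lists that camera did not call at 250 nM in any replicated line still held changed genes. Of 8 anti-apoptotic genes, 5, 6 and 4 were lower (6, 6 and 4 adjusted over the list alone, camera adjusted p = 0.0812, 0.0539 and 0.207). They include MCL1 (above) and XIAP at -0.79 ± 0.15, -1.81 ± 0.15 and -0.97 ± 0.15. Pro-apoptotic genes had 5, 6 and 7 of 16 lower (the same in the list alone, adjusted p = 0.64, 0.962 and 0.654), and p53 target genes 14, 18 and 14 of 25 (15, 18 and 14 in the list alone, adjusted p = 0.0557, 0.0698 and 0.0597). Heat shock genes had 6, 9 and 8 of 20 lower (9, 9 and 9 in the list alone; adjusted p = 0.91, 0.718 and 0.482), and cholesterol synthesis genes 6, 7 and 3 of 16 (the same in the list alone; adjusted p = 0.685, 0.833 and 0.9). HOX genes had 6, 7 and 5 of 17 lower (6, 7 and 6 in the list alone; adjusted p = 0.436, 0.833 and 0.617) and interferon response genes 1, 2 and 4 of 18 (the same in the list alone; adjusted p = 0.257, 0.121 and 0.432).

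**Figure D3:**
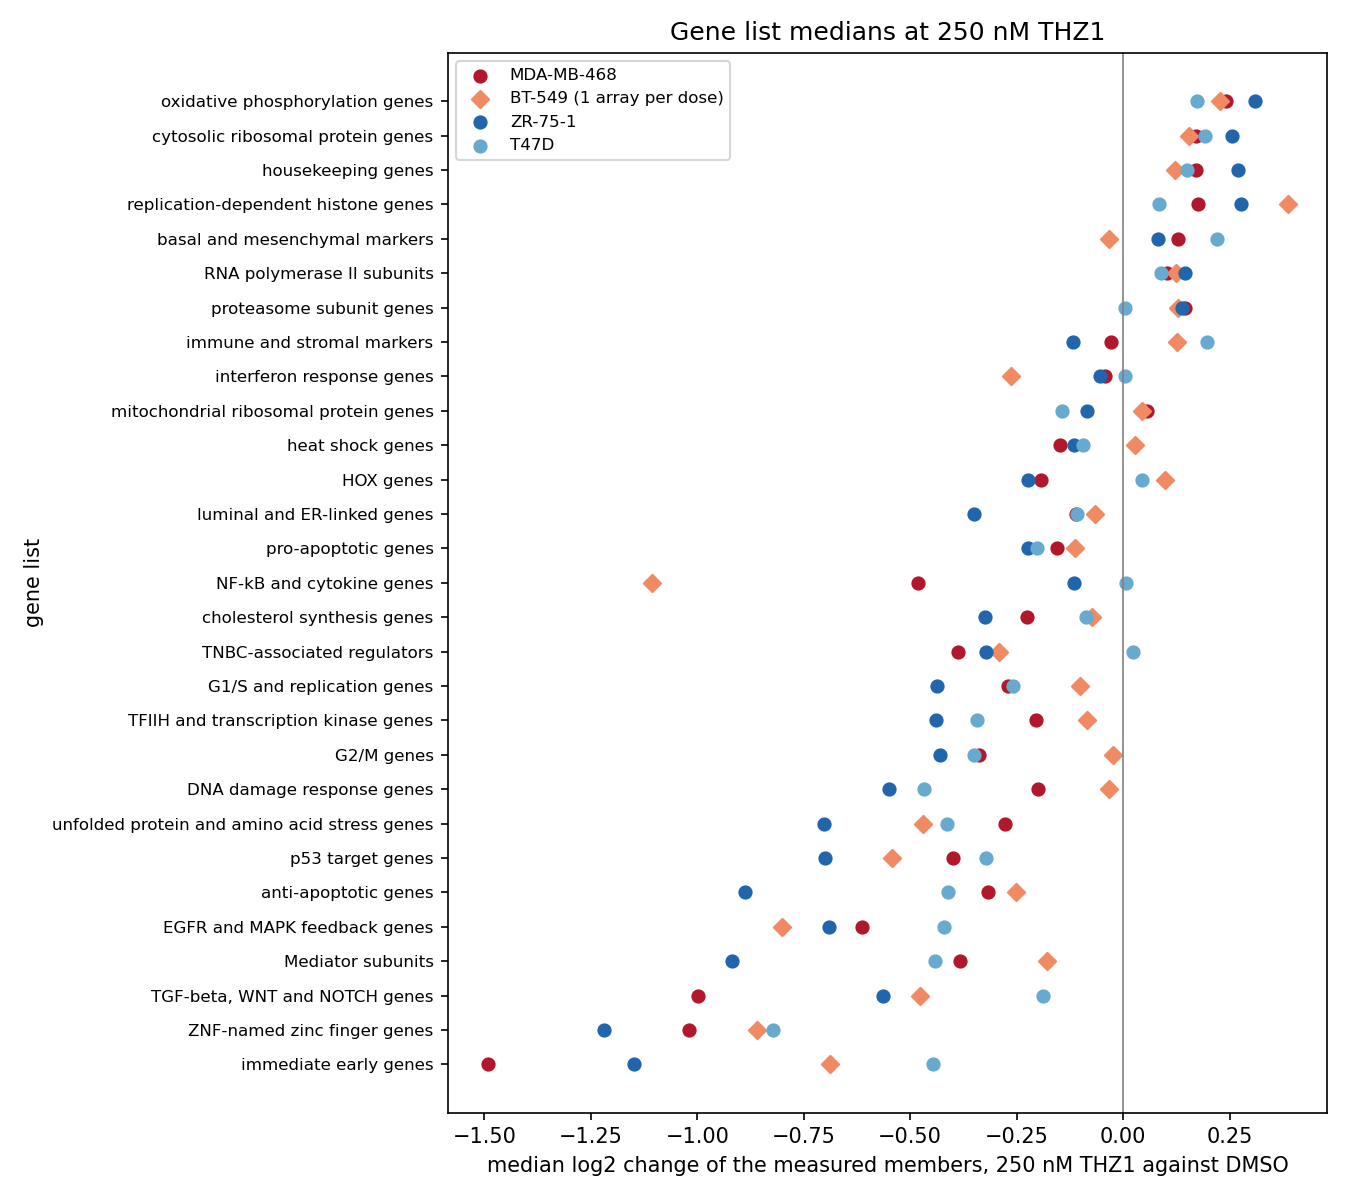
Each row is 1 of the 29 gene lists and each point the median log2 change of its measured members at 250 nM THZ1 in 1 line, from the values as deposited. ZNF-named zinc finger genes lie at -1.02, -1.22, -0.82 and -0.86 and oxidative phosphorylation genes at 0.24, 0.31, 0.17 and 0.23 in MDA-MB-468, ZR-75-1, T47D and BT-549, the sign of the latter turning with arrays scaled to lys, TagJ and TagO.

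At 50 nM, DNA damage response genes and ZNF-named genes were lower as groups in the 3 replicated lines. Of 29 DNA damage response genes, 11, 8 and 7 were lower in MDA-MB-468, ZR-75-1 and T47D (13, 8 and 9 adjusted over the list alone), such as the Fanconi anaemia gene FANCF at -1.44 ± 0.10 and the BRCA1 partner BARD1 at -0.88 ± 0.11 in MDA-MB-468. Camera adjusted p was 0.000339, 0.00512 and 0.000138, and adjusted p = 0.128, 0.22 and 0.112 with an estimated correlation. Of 381 ZNF-named genes, 150, 29 and 55 were lower (177, 32 and 68 adjusted over the list alone; camera adjusted p = 3.12e-09, 0.00515 and 0.000716, adjusted p = 0.129, 0.373 and 0.324 with an estimated correlation). MDA-MB-468 also had 15 of 33 immediate early genes lower (16 adjusted over the list alone; camera adjusted p = 0.0172, adjusted p = 0.362 with an estimated correlation), among them IER3 (-0.65 ± 0.06) and EGR1 (-1.10 ± 0.13), and 9 of 35 G2/M genes (10 adjusted over the list alone; camera adjusted p = 0.0419, adjusted p = 0.573 with an estimated correlation). Oxidative phosphorylation genes passed upward in the 3 lines with 14, 1 and 1 of 79 members called (14, 0 and 1 adjusted over the list alone; camera adjusted p = 6.08e-12, 0.00236 and 9.71e-05, adjusted p = 0.0661, 0.319 and 0.237 with an estimated correlation). In all, camera called 4 lists lower and 5 higher in MDA-MB-468, 2 and 3 in ZR-75-1 and 3 and 6 in T47D, and 0 in each with an estimated correlation.

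From 50 to 250 nM, MYC changed by -3.51 ± 0.08 on the log2 scale in MDA-MB-468 (SE, n = 2 against 2, limma adjusted p = 4.94e-13), by -2.13 ± 0.08 in ZR-75-1 and by -2.07 ± 0.08 in T47D. SOX9 changed by -2.49 ± 0.08, -1.03 ± 0.08 and -1.26 ± 0.08 and MCL1 by -1.93 ± 0.09, -2.01 ± 0.09 and -1.35 ± 0.09 between the doses. limma called 2930 genes lower and 725 higher at 250 than at 50 nM in MDA-MB-468, 5277 and 839 in ZR-75-1, and 3439 and 580 in T47D. Immediate early genes were lower in 20, 24 and 22 of 33 cases (23, 24 and 22 adjusted over the list alone; camera adjusted p = 4.5e-11, 0.000239 and 4.04e-06, adjusted p = 0.0661, 0.236 and 0.136 with an estimated correlation). Genes of TGF-beta, WNT and NOTCH signalling in MDA-MB-468 were lower in 21 of 30 cases (24 adjusted over the list alone; camera adjusted p = 1.05e-06), with adjusted p = 0.0477 with an estimated correlation. Quantile normalization gave 2364 lower and 2350 higher in MDA-MB-468, 3643 and 3817 in ZR-75-1 and 2648 and 2023 in T47D. Median-centring gave 2471 and 1048, 3881 and 2985, and 2765 and 1047. In MDA-MB-468 the higher genes numbered 443 without 50 nM array 1, 303 without 50 nM array 2, 377 without 250 nM array 1 and 446 without 250 nM array 2. In T47D they numbered 277 without 50 nM array 1, 358 without 250 nM array 1 and 216 without 250 nM array 2.

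Many of the same genes changed in the different lines, which have separate DMSO arrays. At 50 nM, 358 genes were called lower in all 3 replicated lines, against 7.92 for independent lists of these sizes, and 351 of them (98%) were also lower in BT-549, where 56.2% of all genes were lower. A further 66 genes were called higher in the 3 lines (0.311 for independent lists). At 250 nM, 2914 genes were called lower in the 3 lines (552 for independent lists), 2679 of them also lower in BT-549, and 454 higher (11.5 for independent lists), 437 of them also higher in BT-549. By pairs, MDA-MB-468 shared 3471 lower genes with ZR-75-1 and 3016 with T47D at 250 nM, against 1639 and 1290 for independent lists.

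In BT-549, 410 genes were at least 2-fold lower and 22 higher at 50 nM, and 1130 and 23 at 250 nM. The log2 changes at 50 and 250 nM were -0.88 and -2.73 for MYC, -0.98 and -2.29 for SOX9, -0.34 and -1.29 for MCL1, -0.29 and -1.09 for CDK7, and -0.88 and -1.25 for CCND1. DKK1 (-4.64), CITED2 (-3.73), FBXO5 (-3.72) and CCN1 (-2.60), among the largest falls of MDA-MB-468, were lower at 250 nM, and H2BC8 was at 2.88. FOXQ1 and CYP1A1, whose DMSO levels were near background in BT-549 (log2 4.62 and 4.95), were at 0.23 and -0.09. Across genes, which are not independent replicates, changes in BT-549 and MDA-MB-468 correlated at r = 0.587 (rho = 0.48) at 50 nM and r = 0.768 (rho = 0.613) at 250 nM. With ZR-75-1 they correlated at r = 0.439 (rho = 0.383) and r = 0.707 (rho = 0.625), and with T47D at r = 0.446 (rho = 0.375) and r = 0.646 (rho = 0.563). Of the 1343 genes at least 2-fold lower in MDA-MB-468 at 250 nM, 1294 (96.4%) were lower in BT-549, with a median of -1.22, as were 92.8% of those of ZR-75-1 and of T47D. At 250 nM the list medians lay at -1.11 for NF-kB and cytokine genes, -0.86 for ZNF-named genes, -0.80 for EGFR and MAPK feedback and -0.69 for immediate early genes, each at percentile 0 of 10000 random lists matched on mean expression, and at 0.39 for replication-dependent histone genes, at percentile 100. These values have no replicate check.

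With the line as the replicate and 4 lines, 3784 genes were lower and 1199 higher at 250 nM (limma, adjusted p under 0.05), 1309 and 2 of them at least 2-fold. MOCS3 fell by a mean log2 change of -3.67 ± 0.29 (SE, limma adjusted p = 8.03e-05), E2F8 by -3.45 ± 0.33, the prostaglandin receptor PTGER4 by -3.15 ± 0.21, the death receptor adaptor FADD by -3.14 ± 0.29, MYC by -2.86 ± 0.30, SOX9 by -1.82 ± 0.29, MCL1 by -1.57 ± 0.16 and FOXA1 by -1.40 ± 0.44. ESR1 (-0.43 ± 0.15, limma adjusted p = 0.0514) did not pass. At 250 nM, MOCS3 was not above background in MDA-MB-468, ZR-75-1 and BT-549, nor E2F8 in MDA-MB-468, T47D and BT-549, which limits their falls. FOXA1 and ESR1 lay below background in BT-549 with DMSO and at 250 nM, so no fall was measurable there. FOXA1 was at 0.61 in BT-549 against -2.41, -2.33 and -1.46 in MDA-MB-468, ZR-75-1 and T47D. In MDA-MB-468, ESR1 stood only 0.27 above background in DMSO. H2BC8 (1.46 ± 0.37) and H2AC17 (1.16 ± 0.14) rose at least 2-fold and MALAT1 rose by 1.00 ± 0.09, with 1 of 3 probe sets opposite in ZR-75-1 and T47D. At 50 nM, 40 genes were lower and 23 higher, among them KRCC1 (-1.91 ± 0.27), MOCS3 (-1.81 ± 0.29), INTS6 (-1.71 ± 0.22), KLF3 (-1.47 ± 0.22) and, upward, PHF12 (1.81 ± 0.25), SSH1 (1.19 ± 0.11) and the Hippo kinase LATS1 (1.02 ± 0.14). Probe sets went the opposite way in MDA-MB-468, ZR-75-1 and T47D for KLF3 (2 of 4 each), INTS6 (1 of 6 each) and SSH1 (2, 1 and 2 of 4), and for PHF12 in MDA-MB-468 (1 of 2, at -0.07 and -0.54 in ZR-75-1 and T47D). KRCC1 was not above background at 50 nM in T47D and BT-549, nor LATS1 in DMSO in MDA-MB-468. MYC was at -0.47 ± 0.30 (limma adjusted p = 0.464). Median-centring gave 3015 lower and 3897 higher genes at 250 nM and 57 and 42 at 50 nM. Quantile normalization gave 2829 and 4128, and 56 and 45. At 50 nM there were 0 lower and 0 higher genes without MDA-MB-468 or without BT-549, 1 and 3 without T47D, 87 and 15 without ZR-75-1, and 1 and 1 with the mean of a gene's probe sets. Leaving out a line also lowers the degrees of freedom, and PHF12 changed by 2.06, 1.77, 1.80 and 1.62 in MDA-MB-468, ZR-75-1, T47D and BT-549. At 250 nM the higher genes numbered 633 without MDA-MB-468 and 776 without ZR-75-1.

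MDA-MB-468 differed from the ER+ lines in its response. At 250 nM, MYC fell more in MDA-MB-468 than in the mean of ZR-75-1 and T47D, by a log2 difference of -2.00 ± 0.10 (SE, limma adjusted p = 8.94e-09). MCL1 differed by -0.47 ± 0.11, with ZR-75-1 (-1.80) close to MDA-MB-468 (-1.98) and T47D at -1.23. The most negative values were those of FOXQ1 (-4.40 ± 0.20, limma adjusted p = 3.41e-09), the matricellular genes CCN2 (-3.11 ± 0.28) and CCN1 (-2.98 ± 0.11), the protease ADAMTS1 (-2.82 ± 0.18), the HLH inhibitor ID4 (-2.74 ± 0.27) and the epithelial factor ELF3 (-2.58 ± 0.13). SOX9 differed by -1.78 ± 0.09. With background at log2 4.76 in ZR-75-1 and 4.69 in T47D, FOXQ1 (4.38 and 4.64) and CCN2 (5.19 and 4.44) had little or no level to lose in DMSO, nor had ID4 in ZR-75-1 (3.70) and ADAMTS1 in T47D (5.36), and CCN1 in ZR-75-1 (6.33) came down to background. There the differences are limited by the level. Lines with a level left showed changes of -1.46 for CCN1, -0.13 for ID4 and -1.14 for SOX9 in T47D, -1.72 for ADAMTS1 in ZR-75-1, and -1.07 and -0.76 for ELF3 in ZR-75-1 and T47D. IFRD1 (2.13 ± 0.11) and the translation factor EIF5 (1.76 ± 0.10) fell in the ER+ lines more than in MDA-MB-468. EIF5 changed by -0.27 in MDA-MB-468, -2.46 in ZR-75-1 and -1.60 in T47D. In BT-549, with 1 array per dose, EIF5 (-1.93) and MCL1 (-1.29) lay between the ER+ lines, and IFRD1 fell less than in either. CCN2, 7.48 above background there in DMSO, changed by 0.08. MYC (-2.73), SOX9 (-2.29), CCN1 (-2.60), ADAMTS1 (-2.22) and ID4 (-2.09) fell further in BT-549 than in either ER+ line. FOXQ1 and ELF3 stood too low there for the fall of MDA-MB-468. The EIF5 and CCN2 differences thus need not be shared by TNBC lines. Against DMSO at 250 nM, ZR-75-1 had 2285 genes at least 2-fold lower, T47D 1194 and MDA-MB-468 1343, so the ER+ mean joins unlike lines. limma called 648 genes lower and 1753 higher in the difference between MDA-MB-468 and this mean. Median-centring gave 566 and 1563, quantile normalization 958 and 1262, and scaling to lys, TagJ and TagO 360 and 2679. Without MDA-MB-468 DMSO array 1 the higher ones numbered 1054. Immediate early genes (18 of 33 lower, 20 adjusted over the list alone) and NF-kB and cytokine genes (5 of 21, 5 adjusted over the list alone) had camera adjusted p = 1.47e-13 and 3.21e-05, and adjusted p = 0.0544 for each with an estimated correlation. TNBC-associated regulators, the list that is not independent evidence and that holds FOXQ1, had 7 of 23 lower (8 adjusted over the list alone, camera adjusted p = 1.6e-05, adjusted p = 0.0328 with an estimated correlation). Besides FOXQ1, its members ETS1 (log2 4.25 and 3.90), SOX11 (3.70 and 4.14) and TGFB2 (4.36 and 4.65) lay below background in DMSO in ZR-75-1 and T47D. No fall of these genes was measurable there, so the DMSO levels set part of the list's difference in advance.

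At 50 nM, 314 genes were lower and 51 higher in MDA-MB-468 than in the ER+ mean (limma, adjusted p under 0.05). The largest differences were those of ZIC5 (-1.67 ± 0.21), CYP1A1 (-1.53 ± 0.16, SE, limma adjusted p = 0.000358), NABP1 (-1.47 ± 0.20) and, upward, the haem oxygenase HMOX2 (1.21 ± 0.10). DMSO levels too low above background to show a fall as large as in MDA-MB-468 were those of ZIC5 in ZR-75-1 and T47D (log2 6.38 and 4.08), CYP1A1 in ZR-75-1 (7.28) and NABP1 in T47D (5.94). MYC differed by -0.58 ± 0.10 (limma adjusted p = 0.00569), a call that ended after median-centring (-0.48). Median-centring gave 124 lower and 79 higher genes. Without MDA-MB-468 DMSO array 1, DMSO array 2, 50 nM array 1 or 50 nM array 2 the lower genes numbered 182, 158, 138 and 122 and the higher ones 20, 93, 11 and 8, and without T47D DMSO array 1, DMSO array 2, 50 nM array 1 or 50 nM array 2 the higher ones were 30, 25, 33 and 32.

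Taking the line as the replicate, 2 TNBC against 2 ER+ lines, GAS1, a growth arrest gene, was lower in the TNBC lines at 250 nM (log2 difference -2.40, limma adjusted p = 0.0318), with changes of -2.44 in MDA-MB-468 and -2.98 in BT-549 against -0.35 in ZR-75-1 and -0.26 in T47D. Its DMSO level in these ER+ lines, log2 4.89 in each, lay next to the background probe sets (4.76 and 4.69), which left little fall to measure. TUBD1 differed by 1.67 (limma adjusted p = 0.0318), with -0.94 and -0.85 in these TNBC lines and -2.56 and -2.57 in the ER+ lines. Its DMSO levels in MDA-MB-468 and BT-549, log2 6.94 and 5.93 with background at 4.67 and 4.65, were too low to show a fall as large, although at 250 nM it still stood 1.20 and 0.27 above background there. ID4 (-2.46), KLF5 (-2.01) and BMP2 (-1.91) did not pass (limma adjusted p = 0.0534, 0.0977 and 0.0977), and BMP2 (4.15 and 4.39) and, in ZR-75-1, ID4 lay below background in DMSO, while KLF5 (6.54 and 5.53) was too low in the ER+ lines to show a fall as large and changed by -0.40 and 0.25 there. KLF5 still stood 1.25 and 0.95 above background in ZR-75-1 and T47D at 250 nM. At 250 nM, 1683 genes had an unadjusted p under 0.05 where 632 are due by chance. At 50 nM limma called 0 genes, with 466 at an unadjusted p under 0.05. An exact permutation test of 2 lines against 2 cannot go below p = 0.333. Median-centring gave 7 lower and 2 higher genes at 250 nM, quantile normalization 8 and 3, no filter on dim genes 2 and 2, and the mean of a gene's probe sets 0 lower.

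Control transcripts that belong to no human gene also moved with the dose. The bacterial and synthetic controls lys, TagJ and TagO were brighter at 250 nM than with DMSO by 0.51 ± 0.06 on the log2 scale in MDA-MB-468, 0.72 ± 0.06 in ZR-75-1 and 0.57 ± 0.06 in T47D (SE from the spread of 2 arrays per group), and by 0.39 in BT-549, and at 50 nM by 0.13, -0.10, 0.22 and 0.05. The controls dap, phe and thr differed by 0.09 ± 0.06, 0.54 ± 0.08 and 0.23 ± 0.02 in MDA-MB-468, ZR-75-1 and T47D, and by 0.34 in BT-549. The hybridisation controls bioB, bioC, bioD and cre differed by 0.02 ± 0.08, 0.13 ± 0.04 and -0.00 ± 0.05 and the background probe sets by 0.13 in each of these lines. With arrays scaled to lys, TagJ and TagO, the median change at 250 nM was -0.58 in MDA-MB-468, -0.89 in ZR-75-1 and -0.64 in T47D, and 11097, 12284 and 11136 genes were called lower (limma). At 50 nM in ZR-75-1 it was 0.10.

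**Figure D4:**
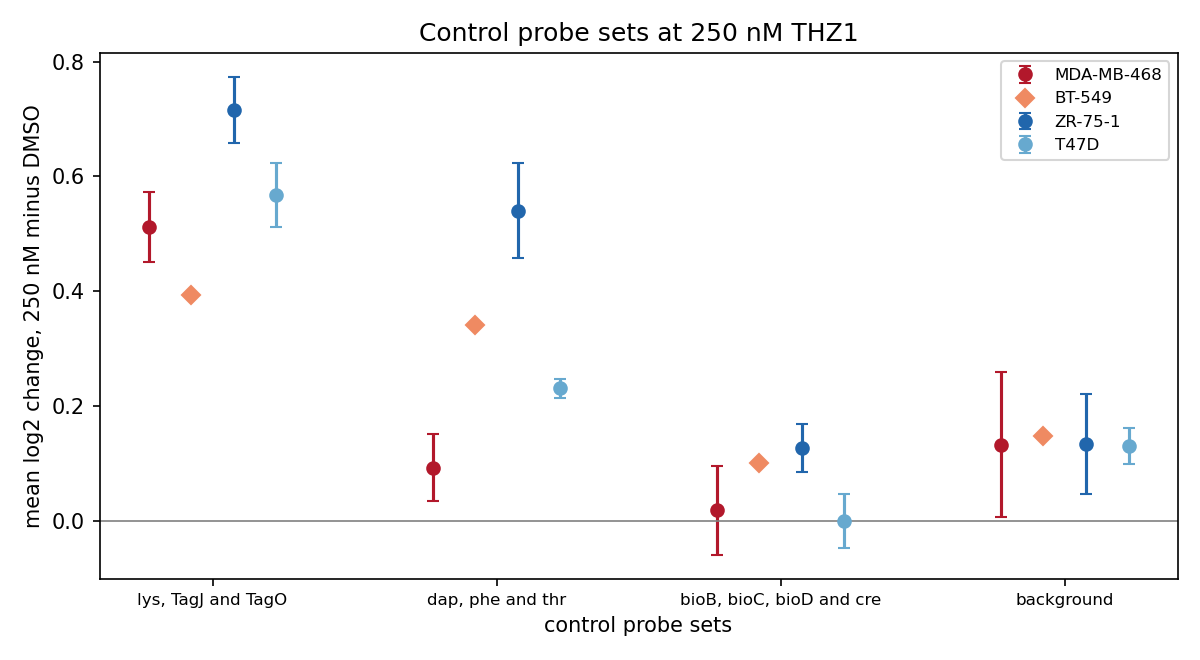
Shown is the mean log2 change of 4 groups of control probe sets at 250 nM THZ1 against DMSO in each line, with the SE from the spread between arrays (none for BT-549, which has 1 array per dose). lys, TagJ and TagO rise by 0.51, 0.72, 0.57 and 0.39 in MDA-MB-468, ZR-75-1, T47D and BT-549, above the hybridisation controls at 0.02, 0.13, -0.00 and 0.10.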

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

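The tests of array brightness and of the dap, phe and thr controls, the test of array scaling for the difference between lines, and the comparison of DMSO levels with background, were chosen after the result was seen. Each gene and gene list below differed between MDA-MB-468 and the mean of ZR-75-1 and T47D in a limma or camera test of the difference itself, and the control transcripts lie outside the genes compared in the report.

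At 50 nM, 314 genes had a lower and 51 a higher change in MDA-MB-468 (limma, adjusted p under 0.05). The 8 most negative differences belonged to ZIC5 (-1.67), CYP1A1 (-1.53), NABP1 (-1.47), the protease gene ADAMTS5 (-1.40), ANKRD1 (-1.33), ZNF254 (-1.24), DKK1 (-1.23) and RNF222 (-1.20). The 8 most positive belonged to HMOX2 (1.21), TENT5C (1.13), KRTAP10-2 (1.00), the interferon-induced MX2 (0.86), the chromosome maintenance gene SMC5 (0.85), ID2 (0.81), the muscarinic receptor CHRM3 (0.81) and LMCD1 (0.80). Among the fixed genes, MYC (-0.58) and SOX9 (-0.44) differed. In DMSO, background stood at log2 4.67 in MDA-MB-468, 4.76 in ZR-75-1 and 4.69 in T47D. ADAMTS5 (4.04 and 3.83) and ANKRD1 (3.66 and 3.98) lay below it in both ER+ lines, ZIC5 in T47D (4.08), RNF222 in ZR-75-1 (3.99) and MX2 in MDA-MB-468 (4.41). There no fall was measurable, and the values of ADAMTS5 and ANKRD1 restate the change in MDA-MB-468. ZIC5 in ZR-75-1 and RNF222 in T47D, 1.62 and 0.51 above background, were too low for the fall of MDA-MB-468 as well. CYP1A1 in ZR-75-1 (7.28) and NABP1 (5.94) and DKK1 (5.39) in T47D were too low to show a fall as large as in MDA-MB-468. The other ER+ line had room for it and changed by -3.56 for CYP1A1, -0.96 for NABP1 and -0.54 for DKK1. ZNF254 in MDA-MB-468 stood 0.95 above background in DMSO and at -0.63 from it at 50 nM, so its change of -1.59 there was only partly measurable. In ZR-75-1 and T47D ZNF254 stood 2.03 and 1.14 above background in DMSO and changed by -0.31 and -0.40. KRTAP10-2 (4.88) was too low in MDA-MB-468 for the fall of T47D. Several of these calls ended without 1 array. ADAMTS5 lost its call without MDA-MB-468 DMSO array 1 (-1.36), DMSO array 2 (-1.44), 50 nM array 1 (-1.45) or 50 nM array 2 (-1.35), and SOX9 without these same arrays (-0.46, -0.41, -0.39 and -0.48). ID2 lost it without DMSO array 1 (0.67), 50 nM array 1 (0.83) or 50 nM array 2 (0.79), TENT5C without DMSO array 1 (1.09) or 50 nM array 2 (1.03), ANKRD1 without 50 nM array 1 (-1.32) or 50 nM array 2 (-1.34), CHRM3 without 50 nM array 1 (0.72) and LMCD1 without 50 nM array 2 (0.61). The replicate number as a block ended the calls of MX2 and SMC5. For 4 genes arrays of the ER+ lines mattered as well. MX2 lost its call without any of the 12 DMSO and 50 nM arrays of the 3 lines, with values from 0.73 to 0.98. KRTAP10-2 lost it without MDA-MB-468 DMSO array 1 (0.95), DMSO array 2 (1.05), 50 nM array 1 (1.08) or 50 nM array 2 (0.91), ZR-75-1 DMSO array 1 (0.85) or 50 nM array 1 (0.95), or T47D DMSO array 1 (0.99), DMSO array 2 (0.999) or 50 nM array 1 (0.89). For SMC5 these were MDA-MB-468 DMSO array 1 (0.69), 50 nM array 1 (0.80) and 50 nM array 2 (0.89), ZR-75-1 DMSO array 1 (0.71) and 50 nM array 1 (0.78), and T47D DMSO array 1 (0.86), DMSO array 2 (0.84) and 50 nM array 2 (0.74). For ZNF254 they were MDA-MB-468 DMSO array 2 (-1.0), 50 nM array 1 (-1.33) and 50 nM array 2 (-1.14), ZR-75-1 50 nM array 1 (-1.18), and T47D DMSO array 2 (-1.18) and 50 nM array 2 (-1.19).

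By list, the median difference at 50 nM was -0.27 for TNBC-associated regulators, -0.18 for immediate early genes, -0.10 for G2/M genes, -0.26 for NF-kB and cytokine genes and -0.21 for ZNF-named genes. It was 0.0272 for cytosolic ribosomal protein genes, 0.0604 for mitochondrial ribosomal protein genes, 0.072 for oxidative phosphorylation genes and 0.0505 for proteasome subunits. All 9 lists passed camera, and none did with an estimated correlation (adjusted p from 0.129 to 0.629). FOXQ1, ETS1, SOX11 and TGFB2 of the TNBC-associated list lay below background in DMSO in both ER+ lines, which limits that list's difference at each dose. At 250 nM, the medians were -0.23 for TNBC-associated regulators, -0.58 for immediate early genes, -0.0576 for unfolded protein and amino acid stress genes, -0.0198 for EGFR and MAPK feedback genes, -0.13 for TGF-beta, WNT and NOTCH genes, -0.35 for NF-kB and cytokine genes, -0.0329 for cytosolic ribosomal protein genes and 0.16 for mitochondrial ribosomal protein genes, of which the first held with an estimated correlation (adjusted p = 0.0328) and the others did not (adjusted p from 0.0544 to 0.705).

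At 250 nM, 648 genes had a lower and 1753 a higher change in MDA-MB-468. The 8 most negative were FOXQ1 (-4.40), CCN2 (-3.11), CCN1 (-2.98), ADAMTS1 (-2.82), ID4 (-2.74), ELF3 (-2.58), the forkhead gene FOXI1 (-2.57) and ZFP42 (-2.30), and the 8 most positive IFRD1 (2.13), FLRT3 (2.06), RIBC2 (1.99), the immediate early gene EGR3 (1.97), MPPED2 (1.97), the decapping factor DCP1B (1.94), SOX18 (1.80) and EIF5 (1.76). The fixed genes MYC (-2.00), SOX9 (-1.78), MCL1 (-0.47), ESR1 (0.57), GATA3 (-0.41), FOXA1 (-0.51, 1 of 2 probe sets opposite) and CCND1 (0.34) differed too. For some of them the ER+ lines were unlike each other. GATA3 changed by -1.40 in MDA-MB-468, -1.64 in ZR-75-1 and -0.34 in T47D, and CCND1 by -0.64, -1.71 and -0.26. MCL1 (-1.98, -1.80 and -1.23) and FOXA1 (-2.41, -2.33 and -1.46) fell in ZR-75-1 nearly as far as in MDA-MB-468. In DMSO, FOXQ1 (log2 4.38 and 4.64) and ZFP42 (3.01 and 3.61) lay below background in ZR-75-1 and T47D, CCN2 in T47D (4.44) and ID4 in ZR-75-1 (3.70), and FOXI1 (5.02 and 5.30), CCN2 in ZR-75-1 (5.19) and ADAMTS1 in T47D (5.36) lay next to it. In MDA-MB-468, FLRT3 (4.44), MPPED2 (3.22) and DCP1B (4.46) lay below background and EGR3 (4.70), SOX18 (4.82) and ESR1 (4.95) next to it, and RIBC2 (5.76) was too low for the fall of the ER+ lines. Little or no fall was measurable there, and the values of FOXQ1, ZFP42, CCN2, FOXI1, FLRT3, MPPED2, DCP1B, SOX18 and ESR1 mostly restate the change in the other lines. In lines with a level left, ID4 (-0.13), CCN1 (-1.46) and SOX9 (-1.14) in T47D, ADAMTS1 in ZR-75-1 (-1.72) and ELF3 in both (-1.07 and -0.76) changed by less than in MDA-MB-468. GATA3 lost its call without MDA-MB-468 DMSO array 1 (-0.39) or 250 nM array 2 (-0.37). ESR1 lost it without MDA-MB-468 DMSO array 1 (0.49), 250 nM array 1 (0.60) or 250 nM array 2 (0.55), ZR-75-1 DMSO array 1 (0.56), DMSO array 2 (0.58) or 250 nM array 2 (0.47), or T47D DMSO array 1 (0.55), DMSO array 2 (0.59) or 250 nM array 1 (0.52). Between the 2 TNBC and the 2 ER+ lines, 1 gene was lower (GAS1, next to background in DMSO in the ER+ lines) and 1 higher (TUBD1, too low in DMSO in the TNBC lines to show the fall of the ER+ lines).

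The excess of higher over lower differences at 250 nM, 1753 against 648, is a pattern to weigh. Array scaling as its whole origin is argued against by quantile normalization, which left 1.32 higher differences per lower one (1.12 to 1.48 leaving out 1 array). A lower DMSO level in MDA-MB-468, leaving less to lose, is argued against by genes whose DMSO level lay within 0.5 log2, with 3 higher differences per lower one (2.52 to 3.8), 778 against 259. Among genes with a lower DMSO level in MDA-MB-468 the ratio was 6.14, so the DMSO level may still contribute. The ER+ mean joins unlike lines. At 250 nM ZR-75-1 had 2285 genes at least 2-fold lower than with DMSO, T47D 1194 and MDA-MB-468 1343. The excess need therefore not be a trait of MDA-MB-468, which was not compared with each ER+ line singly. A biological difference between the lines stays open and was not tested, since MDA-MB-468 is the only replicated TNBC line.

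The rise of the control transcripts lys, TagJ and TagO at 250 nM, by 0.51 in MDA-MB-468, 0.39 in BT-549, 0.72 in ZR-75-1 and 0.57 in T47D, lay above every DMSO array of the same line. Brighter arrays are argued against by the hybridisation controls, whose rise was at most 0.254 of this one in any line, and a raised background by the background probe sets, at most 0.374. Less cellular RNA per cell, against 1 RNA mix that also holds dap, phe and thr, was weighed by the rise of those controls. The bound, chosen afterwards, was 0.5 of the rise of lys, TagJ and TagO. In MDA-MB-468 the share was 0.18, a distance of -0.164 log2 from the bound with an SE of 0.0662. That SE rests on 2 arrays per group, so the value argues only weakly against this explanation in MDA-MB-468. In T47D the share was 0.406, within 2 SE of the bound of 0.5, and at 50 nM these controls rose by 0.23 there against 0.22. In ZR-75-1 the share was 0.755, as this explanation needs, so it stays open in these 2 lines. In BT-549 it was 0.868 on 1 array per dose, which decides nothing. Less RNA per cell may still account for lys, TagJ and TagO alone, since which RNA mix these probe sets detect is not given in the sources used here.

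The response over the 4 lines was tested against splits of the 8 line means that exchange the treated and the DMSO mean within lines. There are 8 of these, too few for a share under 0.05. An exchange in some lines also turns the treatment effect into residual spread. Low counts in the other splits therefore follow from any strong effect and add nothing to the fit itself. At 250 nM, 1 split, the real one, gave as many genes (4983, against 0 in the highest other), and at 50 nM likewise 1 (63, against 0). The other splits of all 35 put both means of some line on the same side, and the highest of all others gave 0 genes at 250 nM and 1 at 50 nM. At 50 nM the real count was 0 without MDA-MB-468 or without BT-549, with fewer degrees of freedom.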

How the results depend on the processing

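Scaling to lys, TagJ and TagO, genes at the filter level in DMSO of each line, the crossed replicate block and the other scalings of the DMSO comparison were chosen after the data were seen. The planned ERCC scaling was not run. A floor of 16 and no trend left all 24 counts within 1.5 times, and the cause of the changes below was not tested unless stated. Leaving out an array gives a group 1 array, which is assumed to vary like the others. Dim genes near the background limit what a fall can show.

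With median-centred arrays, MDA-MB-468 had 1053 lower and 1605 higher genes at 50 nM, 104 of them at least 2-fold lower, and 3479 higher at 250 nM, 14 at least 2-fold. ZR-75-1 at 250 nM had 3625 higher, 23 at least 2-fold, and T47D 615 lower at 50 nM and 2453 higher at 250 nM, 18 at least 2-fold. Higher genes at 250 against 50 nM numbered 2985 in ZR-75-1 and 1047 in T47D. The difference between lines at 50 nM had 124 lower and 79 higher, the 4-line response 42 higher at 50 nM and 3897 at 250 nM, and the subtype difference at 250 nM 7 lower and 2 higher.

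Quantile normalization gave 114 genes at least 2-fold lower in MDA-MB-468 at 50 nM, and at 250 nM 3092 higher (10 at least 2-fold) in MDA-MB-468, 4189 higher (42 at least 2-fold, and 1453 at least 2-fold lower) in ZR-75-1 and 3361 higher (24 at least 2-fold) in T47D, with 532 higher in T47D at 50 nM. Higher genes at 250 against 50 nM numbered 2350, 3817 and 2023 in MDA-MB-468, ZR-75-1 and T47D, those of the 4-line response 45 at 50 nM and 4128 at 250 nM, and the subtype difference had 8 lower and 3 higher. EGFR in T47D at 250 nM turned from -0.22 to 0.0941. By camera, the direction turned for proteasome subunits in ZR-75-1 at 250 against 50 nM (adjusted p = 0.935) and for cytosolic ribosomal protein genes in the difference at 250 nM (adjusted p = 0.718). Lists called higher numbered 11 rather than 35 against DMSO, 6 rather than 18 for 250 against 50 nM and 1 rather than 5 in the differences.

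Arrays scaled to lys, TagJ and TagO gave, at 50 nM, 2987 lower and 133 higher genes in MDA-MB-468 (311 and 9 at least 2-fold), 268 lower in ZR-75-1 (14 lower and 13 higher at least 2-fold) and 4133 lower and 68 higher in T47D (172 and 5). At 250 nM they gave 11097 lower and 8 higher in MDA-MB-468 (2842 and 1 at least 2-fold), 12284 and 6 in ZR-75-1 (5462 and 0 by limma, where 6 genes were higher at any size) and 11136 and 19 in T47D (3307 and 2). The differences had 18 higher genes at 50 nM and 360 lower and 2679 higher at 250 nM. These shifts follow from the scaling itself, which moves every gene of an array by the same amount.

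Without a filter, the subtype difference had 2 lower and 2 higher genes. The filter at the 75th percentile, which tests fewer genes, left 2 genes at least 2-fold higher in MDA-MB-468 and 3 in ZR-75-1 at 250 nM and 16 at least 2-fold lower in ZR-75-1 at 50 nM. With the mean of a gene's probe sets, genes at least 2-fold lower and higher at 50 nM were 110 and 3 in MDA-MB-468, 12 and 1 in ZR-75-1 and 37 and 2 in T47D. At 250 nM, 3 were at least 2-fold higher in ZR-75-1, and 736 lower and 2 higher in T47D, while the 4-line response at 50 nM had 1 lower and 1 higher gene and the subtype difference 0 lower (limma).

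Testing each of 29084 probe sets alone, which tests more features, gave 3473 lower and 1163 higher in MDA-MB-468 at 50 nM (370 and 58 at least 2-fold), 7761 and 2377 at 250 nM (2463 and 14), 1323 and 769 in ZR-75-1 at 50 nM (53 and 42), 11269 and 2738 at 250 nM (4287 and 27), 1873 and 551 in T47D at 50 nM (140 and 47) and 8637 and 2470 at 250 nM (2224 and 55). The 6 arrays of ZR-75-1 alone, fewer samples, gave 339 lower and 121 higher at 50 nM, and array weights gave 233 higher in ZR-75-1 and 396 in T47D at 50 nM.

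With an estimated correlation, camera called 0 lists lower and 4 higher against DMSO (34 and 35 with the preset one), 1 and 2 for 250 against 50 nM (30 and 18) and 1 and 0 in the differences (12 and 5). fry, which does not compare a list with other genes, called 80 lower against DMSO, 60 lower and 11 higher for 250 against 50 nM and 8 higher in the differences. Its direction differed from that of camera for TGF-beta, WNT and NOTCH genes in MDA-MB-468 at 50 nM (fry adjusted p = 0.0201) and, at 250 nM, for mitochondrial ribosomal protein genes in MDA-MB-468 (0.478) and ZR-75-1 (0.000344), RNA polymerase II subunits (0.0213) and heat shock genes (5.43e-06) in ZR-75-1, and TNBC-associated regulators (6.32e-05), NF-kB and cytokine genes (0.000771), cholesterol synthesis genes (0.0156) and HOX genes (0.00615) in T47D. For 250 against 50 nM it differed for DNA damage response genes in MDA-MB-468 (0.000833), for TNBC-associated regulators (3.6e-07), RNA polymerase II subunits (0.00025), heat shock genes (1.22e-06), NF-kB and cytokine genes (6.32e-05) and mitochondrial ribosomal protein genes (0.0012) in ZR-75-1, and for RNA polymerase II subunits (0.0201) and cholesterol synthesis genes (0.0381) in T47D.

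Leaving out a line also lowers the degrees of freedom. Without MDA-MB-468 or without BT-549 the 4-line response at 50 nM had 0 lower and 0 higher genes (limma), without ZR-75-1 87 and 15, and without T47D 1 and 3. At 250 nM, 633 genes were higher without MDA-MB-468 and 776 without ZR-75-1.

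Leaving out 1 array at a time, the lowest and highest counts at 50 nM were 1189 and 1905 lower and 217 and 593 higher in MDA-MB-468, 361 and 754 lower, 135 and 365 higher and 23 and 40 at least 2-fold lower in ZR-75-1, and 443 and 995 lower and 115 and 255 higher in T47D. At 250 nM they were 746 and 1263 higher (5 and 10 at least 2-fold) in MDA-MB-468, 6 and 10 at least 2-fold higher in ZR-75-1, and 664 and 1255 higher (11 and 17 at least 2-fold) in T47D. Higher genes at 250 against 50 nM ranged from 303 to 780 in MDA-MB-468 and from 216 to 621 in T47D. The differences ranged from 122 to 356 lower and 8 to 93 higher at 50 nM and from 1054 to 1831 higher at 250 nM. The arrays behind each change are named in the report.

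Whether replicate numbers pair the arrays cannot be told from 2 arrays per group. Deviations of same-numbered arrays correlated across genes, which are not independent replicates, at r = 0.025, 0.291 and 0.013 in MDA-MB-468, -0.22, 0.029 and 0.169 in ZR-75-1 and 0.019, 0.039 and 0.142 in T47D. With the replicate number as a block, MDA-MB-468 at 250 nM had 3894 lower and 1306 higher genes, and all 41 counts stayed within 1.5 times. The block ended the calls of MX2 (0.86) and SMC5 (0.85) in the difference at 50 nM and of 2 lists for 250 against 50 nM, TNBC-associated regulators in MDA-MB-468 (camera adjusted p = 0.0589) and anti-apoptotic genes in ZR-75-1 (0.0532). It added those of TFIIH and transcription kinase genes in T47D for 250 against 50 nM (0.0424) and of housekeeping genes in the difference at 250 nM (0.0385), and changed no other call among the named genes and the lists. The crossed block in ZR-75-1 gave 725 lower and 356 higher genes at 50 nM and 5470 and 1344 at 250 nM.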

Other observations

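The tests of probe sets that moved apart were chosen after the result was seen, and so were the genes named here. Some genes that rose at 50 nM in MDA-MB-468 were not higher at 250 nM. TENT5C, a noncanonical poly(A) polymerase gene, went from 1.54 to -1.25 on the log2 scale (difference between doses -2.78 ± 0.19, SE, limma adjusted p = 9.89e-09), and PHF12 from 2.06 to 0.22 (difference -1.84 ± 0.13, limma adjusted p = 1.54e-08). In ZR-75-1 PHF12 was at 1.77 and 0.58, while in T47D it was at 1.80 and 1.65 (1 of 2 probe sets opposite at 250 nM), where the doses differed by -0.16 (limma adjusted p = 0.404). ID2, an inhibitor of DNA-binding HLH factors, was at 1.24 and -0.08 in MDA-MB-468 (difference -1.32, limma adjusted p = 1.56e-06).

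Among 7681 genes with at least 2 tested probe sets, 98 had probe sets that moved apart at 50 nM in some replicated line, 1 up and 1 down by at least 0.5 log2, each at a limma adjusted p under 0.05. For the transporter gene ABCC5 1 probe set was lower in MDA-MB-468, ZR-75-1 and T47D (-0.72, -0.63 and -0.56) and 1 with an s suffix was raised (0.95, 1.03 and 0.68). Another was at -0.54, -0.35 and -0.14, which passed only in MDA-MB-468 (limma adjusted p = 0.00537, 0.0978 and 0.573). Noise of single probe sets is argued against by the overlap between lines, at least 20 genes in each pair where random genes with as many probe sets gave at most 3 at the 95th percentile. Probe sets of several genes were left out, so the s or x suffix of shared ones cannot test sharing between genes. It was on 16.3% of the 86 rising probe sets in MDA-MB-468 and 33.1% of others (ratio 0.491). Sharing between transcripts was not counted, and both stay open. A change of isoform or of the polyadenylation site may account for the pattern and stays open, since probe positions were not used here.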
